A study of Mus musculus with 9 samples.

How the data were processed

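White adipose tissue of 9 male mice was profiled on Clariom S mouse arrays: 3 wild type mice (C57BL/6JHamSlc-+/+) given vehicle, 3 ob/ob mice (C57BL/6JHamSlc-ob/ob) given vehicle, and 3 ob/ob mice given 100 mg/kg of Vigna umbellata extract (VE) by gavage for 6 weeks in a study of 42 days, per the labels' protocols. The mice were 6 weeks old when obtained, per the labels' protocols. 100 ng of RNA per sample was labelled with the WT PLUS kit and hybridized for 16 hours, per the series' design text. The depot of the tissue, the genome build and the order of hybridization were not stated. The deposited table holds 1 log2 value per transcript cluster and array, rounded to 2 decimals; the submitters normalized the arrays by SST-RMA (signal space transformation and robust multi-chip analysis) in Transcriptome Analysis Console, version 4.0.2 per the design text and 4 per the submitters' processing notes. The submitters called genes by a one-way ANOVA with an empirical Bayes correction at an unadjusted p under 0.05 and a fold over 1.1, with a detection threshold of 0.05 and an area under the curve of at least 0.7, per the design text. Detection calls and scanner files were not used here, so neither of the last 2 filters could be applied, and no signal over background can be given. Arrays have no read depth, and their number limits the precision.

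The table has 22206 transcript clusters. Of these, 19572 carry exactly 1 gene symbol in the platform annotation, 0 carry several and 2634 are not named there, and the latter were left out of all tests but those named as such. All 19572 matched a gene of the reference table for assembly GRCm38.p6, used for names and genomic spans only, and 0 symbols needed an update. These clusters stand for 19505 genes; 55 genes have several clusters, of which the one with the highest mean over all arrays stands for the gene, and 51 clusters have values identical to another. Values were used as deposited.

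Differences were fitted with limma 3.58.1 in R 4.3.3 as 3 group means over all 9 arrays, with empirical Bayes moderation (prior degrees of freedom 4.02), and p-values were adjusted by Benjamini-Hochberg over the 19572 clusters within each of the 3 comparisons. A call is an adjusted p under 0.05, all tests are two-sided, and a moderated F test covered the 3 groups together. An error given as SE is that of the log2 difference in this fit, and an SD is that of the 3 arrays. 34 gene lists with 659 genes, of which 595 were measured, were fixed before the data were examined, as were the comparisons, the alternatives not marked otherwise and the rule for named genes. Lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists within a comparison, with camera at an estimated correlation and with fry beside it. Camera compares a list's genes with all other genes, while fry tests whether they move on balance. Members were also adjusted over the list alone.

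The rule names, per comparison, the 8 largest increases and the 8 largest decreases among called clusters whose groups do not overlap, filled by the smallest p where fewer passed, the 2 members of each described list with the highest and the 2 with the lowest moderated t, called members with a large fold as examples, and 10 genes fixed in advance. Unnamed gene models and some multigene families were left out of the naming.

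The share of ob/ob differences moved back by VE was compared with 100 simulated data sets in which VE equals ob/ob vehicle, and with values in which each ob/ob vehicle array in turn was held out of the calls. The interval of a share is an exact binomial one (Clopper-Pearson) at 95%. The scripts were tested on simulated data for 19572 genes, in which limma recovered, between ob/ob vehicle and wild type, 0 of 50 genes changed 1.5-fold, 4 of 50 changed 2-fold, 44 of 50 changed 4-fold and 50 of 50 changed 16-fold. Between VE and ob/ob vehicle it recovered 0, 5, 40 and 49 of 50.

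The alternatives were a fit of only the 2 groups compared, the replicate number as a block, a trended prior, a robust prior, no empirical Bayes, array weights, quantile normalization, median centring, the dimmest 30% of clusters left out, every cluster tested, the submitters' threshold, an adjusted p under 0.1, and each array left out in turn. Chosen after seeing the data were a fit without wild type arrays 1 and 2, the mean of the epithelium list as a covariate, and values with each array's trend on log genomic span removed.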

Results

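Transcript levels were measured in white adipose tissue of male mice on 9 Clariom S mouse arrays, 1 array per sample. The 3 groups held 3 arrays each: wild type mice given vehicle, leptin-deficient obese ob/ob mice given vehicle, and ob/ob mice given 100 mg/kg of an extract of Vigna umbellata, the rice bean (VE), by oral gavage for 6 weeks. The series text gives 3 mice per group, and the fat depot was not stated. Array medians lay between 6.11 and 6.26 on the log2 scale, and the number of arrays limits the precision of every value. Pearson's r across genes, which are not independent replicates, was 0.980 to 0.987 between ob/ob vehicle arrays, 0.982 to 0.988 between VE arrays and 0.933 to 0.956 between wild type arrays. The median SD of a gene was 0.407 in wild type, 0.296 in ob/ob vehicle and 0.257 in VE arrays. The first principal component held 59.2% of the variance and set the wild type arrays, at 62.5 to 130.5, apart from the 6 ob/ob arrays, at −58.4 to −38.4. By limma's moderated F test, 3069 of 19572 annotated transcript clusters differed between the 3 groups. Exact permutation of 3 against 3 arrays cannot give a p under 0.1, so calls rest on limma's pooled estimate of the spread.

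Vehicle-treated ob/ob mice were set against wild type mice to describe the adipose transcripts of obese, leptin-deficient animals. Lep, the gene that carries a nonsense mutation in ob/ob mice, read 19.02, 19.24 and 18.77 on the ob/ob vehicle arrays, 18.86, 19.02 and 18.75 on the VE arrays, and 14.22, 13.22 and 16.72 on the wild type arrays. Its probes are not known to cover the mutated base, so this level does not check the genotype. Markers of macrophages showed the broadest difference. Of 23 measured macrophage genes, 21 were higher in ob/ob mice, 0 were lower and 2 did not pass. Gpnmb, a glycoprotein of lipid-laden macrophages, was at 17.60 ± 0.77 (SD, n = 3) in ob/ob vehicle and at 7.55 ± 0.59 in wild type mice, and the macrophage elastase Mmp12 was at 18.93 ± 0.38 and 9.87 ± 0.78. Transcripts of epithelial cells went the other way: 11 of 16 measured members of the epithelium list were lower in ob/ob mice, and the epithelial cadherin Cdh1 was at 5.19 ± 0.13 in ob/ob vehicle against 12.44 ± 2.23 in wild type mice.

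The macrophage list had a median log2 difference of 4.71 (limma camera adjusted p = 1.93e-23; adjusted p = 0.186 with an estimated correlation), and 21 members also passed when adjusted over the list alone. Gpnmb was higher by 10.05 ± 0.43 (log2, SE, n = 3; adjusted p = 2.96e-06 by limma) and Mmp12 by 9.06 ± 0.39. The galectin Lgals3 was higher by 8.74 ± 0.44, the lysosomal proton pump subunit Atp6v0d2 by 8.80 ± 0.57 and the lipid receptor Trem2 by 6.16 ± 0.42. The integrin Itgax (CD11c) was higher by 4.93 ± 0.39. General macrophage markers were higher too, with Adgre1 (F4/80) at 4.63 ± 0.42, Csf1r at 3.88 ± 0.58 and Cd14 at 3.68 ± 0.40. Lyve1 (1.03 ± 1.06; adjusted p = 0.588 by limma) and Cd163 (−0.97 ± 0.48; adjusted p = 0.218), both found on resident macrophages, did not pass. Beside this group, the epithelium list was lower by a median of −3.05. Without wild type arrays 1 and 2, which held most of the epithelial signal, the macrophage list's median was 3.92. That fit has a lone wild type array, so it gives an effect size only.

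Among 27 inflammatory cytokines and chemokines, 10 were higher, 0 were lower and 17 did not pass (12 higher and 1 lower adjusted over the list alone). The list's median was 0.61 (limma camera adjusted p = 8.46e-06; adjusted p = 0.215 with an estimated correlation). The interleukin 1 receptor antagonist Il1rn was higher by 6.81 ± 0.51 (SE, n = 3), the chemokines Ccl9 by 5.35 ± 0.46, Ccl2 by 5.45 ± 0.49 and Ccl3 by 4.81 ± 0.53, and Tnf by 2.29 ± 0.22 (adjusted p = 1.42e-04 by limma). Nos2 did not pass (−0.40 ± 0.34). Ptgs2, which encodes cyclooxygenase 2, missed the threshold at −8.46 ± 2.73 (adjusted p = 0.0683 by limma) and passed without wild type array 3, at −12.54 (adjusted p = 2.16e-05 by limma). Wild type Ptgs2 was at 14.51 ± 7.07 (SD, n = 3). That signal lay on wild type arrays 1 and 2, which held most of the epithelial signal. Among 27 genes of oxidative stress and NRF2, 14 were higher, 1 was lower and 12 did not pass (16 higher and 4 lower adjusted over the list alone). That list's median was 1.15 (camera adjusted p = 8.46e-06; adjusted p = 0.215 with an estimated correlation). Its members with the largest t were heme oxygenase Hmox1 at 6.91 ± 0.58 and Ncf1 at 3.45 ± 0.31; Ncf1 and Cybb, at 4.87 ± 0.47, encode parts of the phagocyte NADPH oxidase. The glutathione transferase Gsta4 was lower at −1.98 ± 0.30, and the peroxidase Gpx3 did not pass at −1.67 ± 0.61 but passed without wild type array 1 (−2.18, adjusted p = 0.0497 by limma) or 3 (−2.08, adjusted p = 0.0441). The epithelium list, at −3.05, and the macrophage list, at 4.71, moved with both groups.

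Cell division genes were higher: 11 of 19 passed, 0 were lower and 8 did not pass (15 adjusted over the list alone), with a median of 1.73 (limma camera adjusted p = 1.4e-10; adjusted p = 0.215 with an estimated correlation). The cyclins Ccnb2 and Ccna2 were higher by 2.57 ± 0.32 (SE, n = 3) each, Ube2c by 3.77 ± 0.61 and the proliferation marker Mki67 by 3.48 ± 0.55. Rrm2 (1.10 ± 0.49) and Top2a (0.74 ± 0.35) did not pass. Of 29 genes of extracellular matrix, 12 were higher, 0 were lower and 17 did not pass (14 adjusted over the list alone), with a median of 1.23 (camera adjusted p = 3.95e-06; adjusted p = 0.539 with an estimated correlation). Thrombospondin Thbs1 was higher by 5.20 ± 0.35, the collagen crosslinking enzyme Lox by 4.55 ± 0.49 and the protease inhibitor Timp1 by 3.58 ± 0.58, while Tgfb2 (−0.88 ± 0.57) and elastin Eln (−0.57 ± 0.22) did not pass. Beside these 2 groups the macrophage list stood at 4.71 and the epithelium list at −3.05.

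Of 20 genes of mitochondrial and peroxisomal fatty acid oxidation, 10 were higher, 0 were lower and 10 did not pass (13 adjusted over the list alone), with a median of 1.16 (limma camera adjusted p = 5.41e-06; adjusted p = 0.496 with an estimated correlation). Cpt1a, which controls fatty acid entry into mitochondria, was higher by 1.64 ± 0.23 (SE, n = 3) and the dehydrogenase Acads by 1.84 ± 0.28; Eci1 (−0.02 ± 0.32) and Acot2 (−0.25 ± 0.32) did not pass. Of 15 adipokines, 5 were higher, 0 were lower and 10 did not pass (5 higher and 1 lower adjusted over the list alone), with a median of 0.057, a mean of 1.27 and a camera adjusted p of 0.0296 (adjusted p = 0.677 with an estimated correlation). Lep was higher by 4.29 ± 0.69, or 19.6-fold (adjusted p = 0.00276 by limma), Sfrp5 by 7.28 ± 0.29, Metrnl by 4.10 ± 0.29 and Angptl4 by 2.99 ± 0.39. Lep read 14.22 and 13.22 on wild type arrays 1 and 2 but 16.72 on array 3, so its fold depends on the wild type arrays used. Resistin Retn (−1.66 ± 0.70; adjusted p = 0.149) and Nampt (−0.71 ± 0.25) did not pass, and Retn passed without ob/ob vehicle array 1 (−2.46, adjusted p = 0.0286 by limma). Adiponectin Adipoq (0.06 ± 0.28), Pparg (0.45 ± 0.47), Fasn (0.71 ± 0.65), the glucose transporter Slc2a4 (0.22 ± 0.51) and Ucp1 (0.66 ± 0.32) did not pass. The epithelium list, at −3.05, and the macrophage list, at 4.71, moved with these genes. Without wild type arrays 1 and 2, which leaves a lone wild type array, the median of fatty acid oxidation was 0.55. The adipokine call ended without ob/ob vehicle array 1 (camera adjusted p = 0.0751), wild type array 1 (0.094) or wild type array 2 (0.123).

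Of the epithelium list, 11 members were lower, 0 were higher and 5 did not pass (13 adjusted over the list alone), with a median of −3.05 (limma camera adjusted p = 9.49e-10; adjusted p = 0.215 with an estimated correlation). Cdh1 was lower at −7.25 ± 0.86 (SE, n = 3) and the epithelial adhesion molecule Epcam at −6.04 ± 0.40, while the keratins Krt10 (−0.01 ± 0.23) and Krt14 (−0.27 ± 0.39) did not pass. The list's array medians were 8.23, 8.32 and 5.74 in wild type and 4.24 to 4.68 on the 6 ob/ob arrays. Against wild type array 3 alone the list's median difference was −1.26. The list of epididymis and testis had a median of −0.93 (camera adjusted p = 0.0487; adjusted p = 0.677 with an estimated correlation) with 0 of 19 members past the threshold of limma and 0 adjusted over the list alone; that camera call ended without wild type array 1, 2, ob/ob vehicle array 1, 2 or VE array 1 or 3, at adjusted p from 0.0517 to 0.158. The largest increases by the fixed rule were those of Gpnmb, Mmp12, Atp6v0d2 and Lgals3 above, of the choline transporter Slc5a7 (10.03 ± 0.67), of Gpr50 (8.93 ± 1.32), Tm4sf19 (8.53 ± 0.46) and Lilr4b (7.40 ± 0.35). The largest decreases were those of Cuzd1 (−8.74 ± 1.5), Pdzk1ip1 (−8.11 ± 0.36), the smooth muscle calponin Cnn1 (−7.76 ± 1.70), Prom1 (−7.63 ± 0.64), Anxa13 (−7.27 ± 1.94), Cdh1, the urogenital transcription factor Pax8 (−7.14 ± 0.74) and the kinesin Kif5c (−6.76 ± 1.92). Anxa13 and Kif5c rest on wild type arrays 1 and 2, since without both they stood at −1.19 (adjusted p = 0.0705 by limma) and −0.77 (adjusted p = 0.287). Their calls also ended without any 1 of the 9 arrays except wild type array 3, at adjusted p up to 0.0978 and 0.126, and that of Cnn1 ended without ob/ob vehicle array 2 (adjusted p = 0.0589 by limma). Wild type signal was uneven as well for Cuzd1 (13.67 ± 4.07, SD, n = 3) and Cnn1 (12.80 ± 4.49), so the sizes of their decreases depend on the wild type arrays used.

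In all, 2754 transcript clusters passed a limma adjusted p of 0.05 in this comparison, 1766 higher and 988 lower in ob/ob mice, and 1648 and 876 of these differed more than 2-fold. At the submitters' threshold 3067 were higher and 2488 lower. Groups did not overlap at 5647 clusters, or 28.9%, against 10% by chance. Camera called 12 of 34 lists, 9 higher and 3 lower, 0 with an estimated correlation, and fry, which tests whether a list's genes move on balance, called 11. The other called lists were adipocyte identity (median 0.54, 5 of 18 higher and 1 lower, camera adjusted p = 0.00274, 0.677 with an estimated correlation), the unfolded protein response (0.31, 2 of 17 higher, 0.049, 0.539 with an estimated correlation) and visceral depot patterning (−0.60, 2 of 11 lower, 0.0381, 0.539 with an estimated correlation). The lists not called had medians of 0.51 for fatty acid synthesis, 0.60 for lipolysis, 0.18 for brown and beige adipocyte genes, −0.20 for oxidative phosphorylation, −0.037 for the interferon response, 0.22 for insulin signalling, 0.60 for cholesterol synthesis, −0.17 for the circadian clock, 0.20 for hypoxia and 0.26 for immediate early genes. Among lists of other cell types not called, medians were 0.097 for B cells, 0.23 for T and NK cells and 0.078 for neutrophils. They were 0.0033 for mast cells, −0.23 for skeletal muscle, −0.12 for mesothelium, 0.32 for endothelium and −0.09 for erythroid cells. They were 0.51 for stromal progenitors, −0.092 for pancreas acinar cells, −0.36 for Schwann cells and 0.15 for subcutaneous depot patterning. Few genes of some lists exceeded the array median on all ob/ob arrays. These numbers were 2 of 13 for B cells, 2 of 17 for T and NK cells and 1 of 14 for neutrophils. They were 2 of 7 for erythroid, 1 of 14 for pancreas acinar, 4 of 13 for mast and 3 of 12 for Schwann cells. For skeletal muscle and for brown and beige adipocyte genes they were 4 of 20 and 4 of 17. Medians near 0 in lists this dim cannot show that such cells did not differ. Without wild type arrays 1 and 2, an alternative chosen after seeing the data that assumes the lone wild type array to vary like the other groups, 2203 clusters passed, 1503 of them among the 2754, and camera called 8 lists. The 5 lists it no longer called were those of adipocyte identity, adipokines, the unfolded protein response, visceral depot patterning, and epididymis and testis, and the medians of adipokines (−0.36) and of epididymis and testis (0.047) changed sign. Cholesterol synthesis was newly called there, at 0.94 (camera adjusted p = 0.0217). Without ob/ob vehicle array 2 the count was 1641 and visceral depot patterning was not called (adjusted p = 0.132), nor was it without wild type array 2 (0.114). The unfolded protein response was not called without ob/ob vehicle array 2 or 3, VE array 1 or 3, or wild type array 1, at adjusted p from 0.0604 to 0.233. Without wild type array 3, the lists of fatty acid synthesis (0.81, camera adjusted p = 0.00964), lipolysis (0.87, 0.019) and stromal progenitors (0.72, 0.0368) were called. That fit keeps wild type arrays 1 and 2, which held most of the epithelial signal. Without ob/ob vehicle array 1 oxidative phosphorylation was called (−0.30, camera adjusted p = 0.0499). Of the 22 alternatives run on lists, 2 called oxidative phosphorylation in this comparison, with a lowest adjusted p of 0.00704. With each array's mean of the epithelium list as a covariate, also chosen after seeing the data, 362 clusters passed, and Lep stood at −0.60 (adjusted p = 0.78 by limma).

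**Figure D1:**
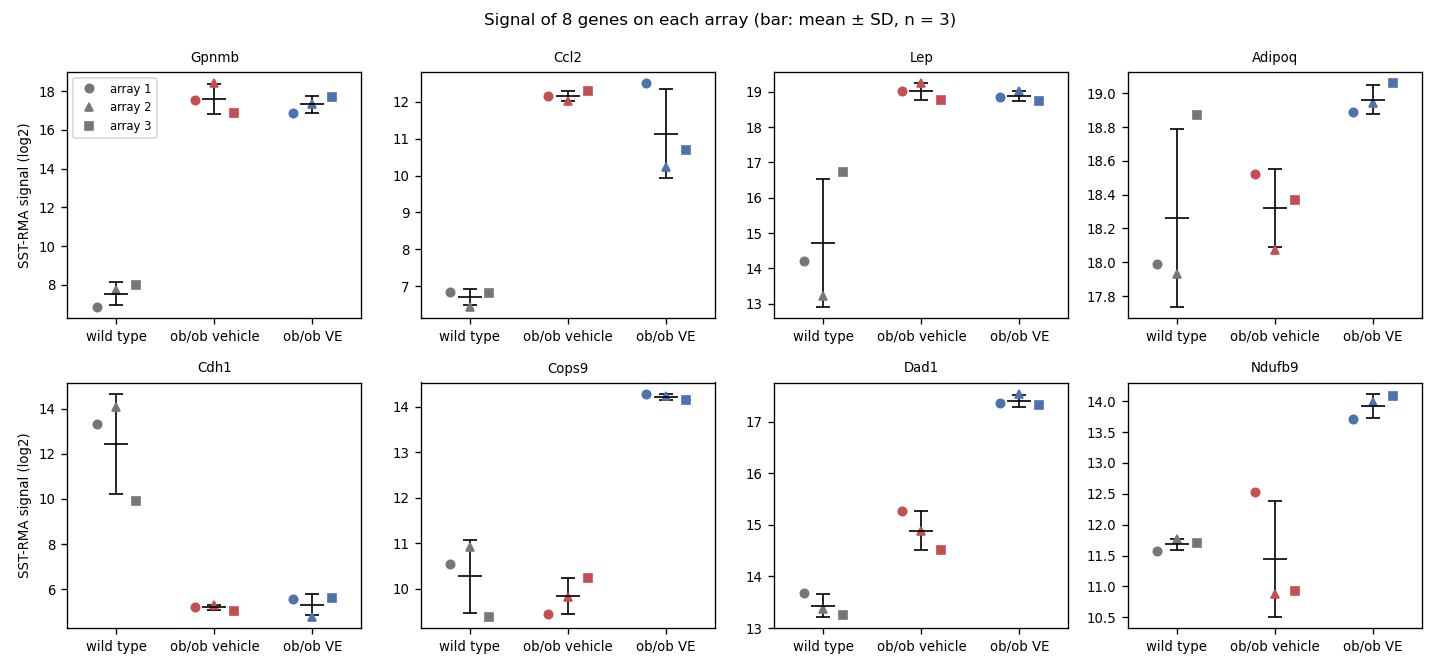
SST-RMA signal (log2, vertical axis) of 8 genes on each array, by group. Points are single arrays, with a symbol for each array number, and bars give the mean ± SD (n = 3). Gpnmb, Ccl2 and Lep were higher on all 6 ob/ob arrays than on the wild type arrays, Cdh1 was lower, and Cops9, Dad1 and Ndufb9 were higher on the 3 VE arrays than on the 3 ob/ob vehicle arrays.

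VE-treated ob/ob mice were set against vehicle-treated ob/ob mice to find the transcripts that differ with the extract. 5 genes passed the limma threshold, and all 5 were higher in VE, on each of the 3 VE arrays above each ob/ob vehicle array. These calls depend on the model: 0 genes passed with the replicate number as a block, where adjusted p by limma was 0.0546 for Cops9 and Dad1 and 0.19 to 0.191 for the other 3, and 0 passed without empirical Bayes (893 had an unadjusted p under 0.05 in limma). More passed under other alternatives: 41 with array weights, 19 with only the 2 groups compared and 12 with a robust prior. Cops9, a small subunit of the COP9 signalosome, was at 14.22 ± 0.066 (SD, n = 3) in VE and at 9.84 ± 0.39 in ob/ob vehicle, 20.8-fold higher. Dad1, a subunit of the oligosaccharyltransferase, was at 17.41 ± 0.12 against 14.89 ± 0.38. Of 31 genes of oxidative phosphorylation, 0 passed on their own and 30 had a difference above 0, with a median of 0.55; camera called the list at its preset correlation, but not with an estimated one (adjusted p = 0.396), and fry did not (adjusted p = 0.117). The measured macrophage list, of which 21 of 23 genes were higher in ob/ob vehicle than in wild type mice, had a median difference of −0.013, and 0 of 23 passed.

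Cops9 was higher by 4.38 ± 0.38 (log2, SE, n = 3; adjusted p = 0.00739 by limma) and Dad1 by 2.52 ± 0.25 (adjusted p = 0.0147). Ppdpf was higher by 2.85 ± 0.33 (adjusted p = 0.0336 by limma), Micos10, a part of the complex that shapes mitochondrial cristae, by 2.24 ± 0.26 (adjusted p = 0.0336), and Naa38, a subunit of an N-terminal acetyltransferase, by 2.31 ± 0.28 (adjusted p = 0.035). In wild type mice these genes read 10.28 ± 0.80 for Cops9, 13.43 ± 0.22 for Dad1, 6.81 ± 0.49 for Ppdpf, 12.34 ± 0.36 for Micos10 and 9.70 ± 0.32 for Naa38. Next by p, and not past an adjusted p of 0.05, came the ATP synthase subunit Atp5g1 (2.71 ± 0.35; adjusted p = 0.0532 by limma), Wdr74 (2.15 ± 0.30; adjusted p = 0.0589) and Ift20 (1.97 ± 0.27; adjusted p = 0.0589). Without ob/ob vehicle array 1 Atp5g1 (adjusted p = 0.045 by limma) and Wdr74 (0.0166) passed, and Atp5g1 also did without wild type array 3 (0.027). All 3 passed with only the 2 groups compared, at adjusted p from 0.0303 to 0.0442 by limma. No gene was lower past the threshold. The lower genes with the smallest p, which all missed it, were Pramel47 (−1.12 ± 0.21), Sprr2j-ps (−2.17 ± 0.45), Cfap100 (−1.11 ± 0.25), C2cd4a (−1.42 ± 0.33), Rph3a (−1.02 ± 0.24), Rasal1 (−0.93 ± 0.22), Atp8b3 (−1.25 ± 0.29) and Sncb (−0.84 ± 0.21), at adjusted p from 0.249 to 0.528 by limma. Naa38 did not pass without wild type array 1 (adjusted p = 0.0535 by limma). Without ob/ob vehicle array 2, or without any 1 VE array, 0 genes passed, 1 passed without ob/ob vehicle array 3 and 21 without ob/ob vehicle array 1. Cops9 missed the threshold without ob/ob vehicle array 2 (adjusted p = 0.0997 by limma) and without any 1 VE array, at adjusted p from 0.0831 to 0.0979 by limma. At an unadjusted p under 0.05 there were 893 clusters, against 978.6 expected by chance. The fit pools the spread with the wild type arrays, where the median SD was 0.407, against 0.296 in ob/ob vehicle and 0.257 in VE. The expected number is thus only a rough reference, and the lower count does not show that VE had no effect.

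The oxidative phosphorylation list had a limma camera adjusted p of 8.1e-18 (adjusted p = 0.396 with an estimated correlation; fry adjusted p = 0.117). Of its 31 members 0 passed over all genes, and 7 passed adjusted over the list alone. Ndufb9, a subunit of complex I, was at 13.93 ± 0.20 (SD, n = 3) in VE, 11.44 ± 0.94 in ob/ob vehicle and 11.68 ± 0.092 in wild type mice, a difference of 2.48 ± 0.40 between VE and vehicle (SE; adjusted p = 0.107 by limma). It passed without ob/ob vehicle array 1 (3.03, adjusted p = 0.0104 by limma) and with array weights (adjusted p = 0.00745). The ATP synthase subunit Atp5b differed by 1.34 ± 0.27 (adjusted p = 0.32), Cs by 0.02 ± 0.26 and Ndufb8 by −0.22 ± 0.24. Array medians of the list were 12.57, 12.68 and 12.35 in VE, 12.28, 11.40 and 11.50 in ob/ob vehicle, and 11.58, 11.60 and 11.70 in wild type. In this comparison the macrophage list (−0.013) and the epithelium list (0.017) had medians near 0, and 2 families chosen after seeing the data had medians of 0.51 (63 genes of cytosolic ribosomal proteins) and 0.40 (76 of mitochondrial ones). In these 0 genes passed limma's threshold, and camera with an estimated correlation gave an unadjusted p of 0.0724 and 0.0535.

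3 more lists were called higher in VE by limma camera, each with 0 members past the threshold over all genes. Of the 10 splits of these arrays, 9 gave at least the 4 called lists, the real one included. The number of lists called thus does not set VE apart from vehicle. Fatty acid oxidation had a median of 0.16 and 18 of 20 members above 0 (camera adjusted p = 0.00829; adjusted p = 0.944 with an estimated correlation; 0 passed adjusted over the list alone). Slc25a20 differed by 0.67 ± 0.28 (SE, n = 3), Acot2 by 0.74 ± 0.32, Cpt2 by −0.047 ± 0.44 and Hadhb by −0.037 ± 0.29. Oxidative stress and NRF2 genes had a median of 0.19 and 16 of 27 members above 0 (camera adjusted p = 0.0173; adjusted p = 0.944 with an estimated correlation; 2 higher adjusted over the list alone). Gpx1 differed by 1.01 ± 0.26, metallothionein Mt2 by 1.79 ± 0.47, Gsta4 by −0.30 ± 0.30 and Ncf1 by −0.46 ± 0.31. Adipokines had a median of 0.32 and 11 of 15 members above 0 (camera adjusted p = 0.0476; adjusted p = 0.944 with an estimated correlation; 0 passed adjusted over the list alone). Resistin Retn differed by 2.53 ± 0.70, adiponectin Adipoq by 0.64 ± 0.28, Sfrp5 by −0.26 ± 0.29 and Angptl4 by −0.44 ± 0.39. With quantile normalization, or with the dimmest 30% of clusters left out, camera called only the oxidative phosphorylation list. Without VE array 3 none of these 3 lists was called (adjusted p = 0.0633 for fatty acid oxidation, 0.276 for NRF2 and 0.1 for adipokines), and without VE array 1 camera called 11 of the 34 lists. Fatty acid oxidation was also not called without ob/ob vehicle array 1 (0.11), NRF2 without ob/ob vehicle array 3 (0.496, with the median turned to −0.11), and adipokines without ob/ob vehicle array 2 (0.172) or 3 (0.258), VE array 2 (0.0545) or wild type array 1 (0.0508). Medians of the macrophage and epithelium lists were −0.013 and 0.017.

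None of the genes fixed in advance passed limma's threshold between VE and vehicle. Tnf differed by −0.63 ± 0.22 (SE, n = 3; adjusted p = 0.961 by limma), Ccl2 by −1.01 ± 0.49, Adgre1 by −0.61 ± 0.42, Itgax by 0.13 ± 0.39, Lep by −0.13 ± 0.69, Pparg by 0.28 ± 0.47, Ucp1 by −0.55 ± 0.32, Fasn by −0.30 ± 0.65 and Slc2a4 by 0.49 ± 0.51. Of the macrophage list, Trem2 differed by 1.15 ± 0.42, Fcer1g by 1.36 ± 0.52, Cd5l by −0.41 ± 0.25 and Msr1 by −0.47 ± 0.25. Medians of lists not called were −0.17 for inflammatory cytokines, −0.057 for extracellular matrix, −0.11 for cell division, 0.14 for lipolysis, 0.065 for fatty acid synthesis, 0.17 for adipocyte identity, 0.12 for brown and beige adipocyte genes, 0.098 for insulin signalling and −0.35 for epididymis and testis. Without VE array 1, which read 12.5 for Ccl2 against 10.2 and 10.7 on the other VE arrays, limma camera called 5 lists lower in VE: inflammatory cytokines (−0.25, adjusted p = 0.00739), cell division (−0.37, 8.96e-04), extracellular matrix (−0.35, 8.96e-04), stromal progenitors (−0.42, 0.0025) and cholesterol synthesis (−0.49, 0.0185). It then called 6 lists higher: the 4 above, lipolysis (0.16, 0.0185) and adipocyte identity (0.19, 0.0382). Lipolysis was also called higher without wild type array 2 (0.14, 0.0351), 3 (0.0231), or 1 and 2 together (0.0213). Lists also called lower with 1 array left out were immediate early genes (−0.31, 2.67e-04, without ob/ob vehicle array 3), mesothelium (−0.53, 0.00657, without VE array 3), and epididymis and testis (−0.49, 0.0118, without ob/ob vehicle array 2; −0.35, 0.0299, without wild type array 2; 0.00951 without wild type arrays 1 and 2). With an estimated correlation camera called 0 of the 34 lists, and fry called 0. On simulated data with the spread of these arrays, limma recovered 40 of 50 genes changed 4-fold and 5 of 50 changed 2-fold in this comparison.

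**Figure D2:**
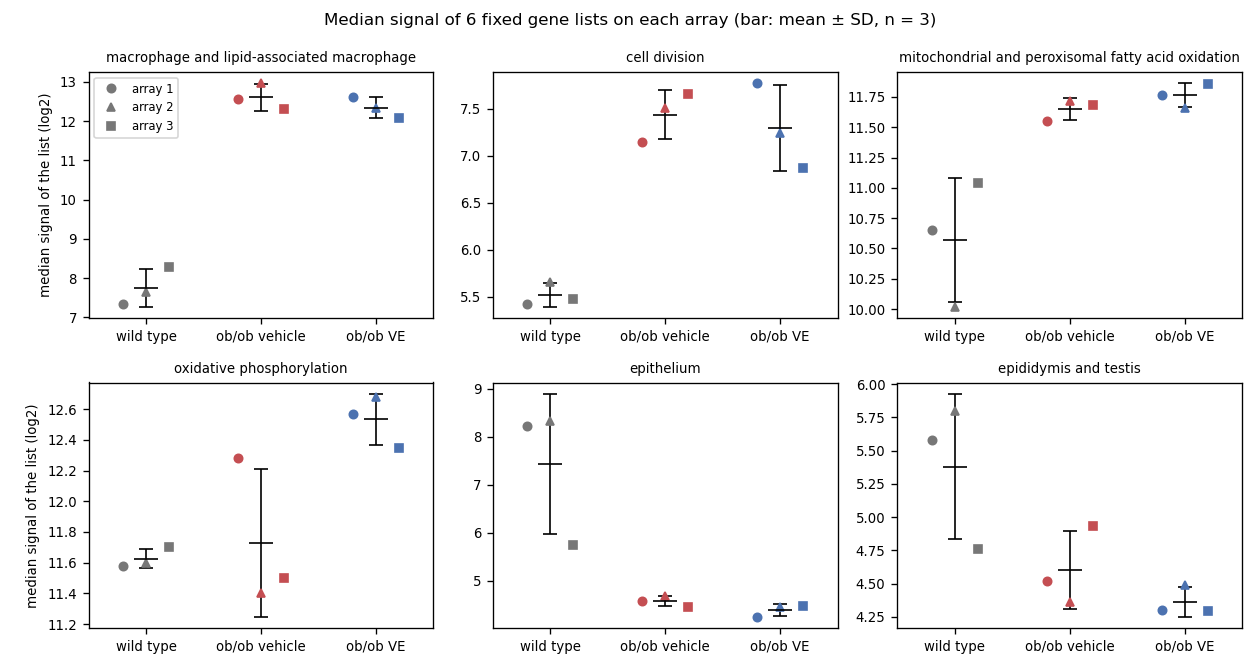
Median SST-RMA signal (log2, vertical axis) of the measured members of 6 gene lists on each array, by group. Points are single arrays, with a symbol for each array number, and bars give the mean ± SD (n = 3). The macrophage list lay at 12.08 to 12.97 on the 6 ob/ob arrays and at 7.34 to 8.29 on the wild type arrays; the oxidative phosphorylation list was highest on the 3 VE arrays, by 0.07 over ob/ob vehicle array 1.

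VE-treated ob/ob mice were also set against wild type mice, to describe the treated animals beside lean ones. Macrophage transcripts were again far higher: 20 of 23 measured members were higher, 0 were lower and 3 did not pass. Lgals3 was at 16.06 ± 0.28 (SD, n = 3) in VE against 6.37 ± 0.87 in wild type mice, and Gpnmb at 17.32 ± 0.43 against 7.55 ± 0.59. Of 31 genes of oxidative phosphorylation, 10 were higher and 2 were lower in VE-treated than in wild type mice. Of 16 epithelial genes, 12 were lower.

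The macrophage list had a median of 4.28 (limma camera adjusted p = 2.08e-20; adjusted p = 0.256 with an estimated correlation), and 21 members passed adjusted over the list alone. Gpnmb was higher by 9.77 ± 0.43 (SE, n = 3), Lgals3 by 9.69 ± 0.44 (adjusted p = 3.32e-06 by limma), Mmp12 by 8.93 ± 0.39, Trem2 by 7.31 ± 0.42, Adgre1 by 4.01 ± 0.42 and Itgax by 5.06 ± 0.39. Lyve1 (0.37 ± 1.06) and Cd163 (−0.30 ± 0.48) did not pass. The chemokine Ccl2 was higher by 4.44 ± 0.49 and Tnf by 1.66 ± 0.22. Oxidative stress and NRF2 genes were higher at 16 of 27 and lower at 2, while 9 did not pass (18 and 2 adjusted over the list alone), with a median of 1.67 (camera adjusted p = 5.02e-07; adjusted p = 0.286 with an estimated correlation). Hmox1 was higher by 6.49 ± 0.58, Mt2 by 4.41 ± 0.47 and Ncf1 by 2.98 ± 0.31, and Gsta4 (−2.29 ± 0.30) and Gpx3 (−2.00 ± 0.61; adjusted p = 0.044 by limma) were lower. The call of Gpx3 ended without any 1 of the ob/ob vehicle or VE arrays, at adjusted p from 0.0635 to 0.116. Beside both groups the epithelium list had a median of −2.91.

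Of the 31 oxidative phosphorylation genes 19 did not pass, and 12 higher and 3 lower passed adjusted over the list alone, with a median of 0.52 (limma camera adjusted p = 0.014; adjusted p = 0.651 with an estimated correlation). Idh3a, of the citrate cycle, was higher by 2.45 ± 0.32 (SE, n = 3), Ndufb9 by 2.25 ± 0.40 and Cox6a1 by 2.5 ± 0.47 (adjusted p = 0.00553 by limma), while Ndufa5 (−1.23 ± 0.22) and Ndufv1 (−0.79 ± 0.21) were lower. Quantile normalization left the list's median at 0.026 (adjusted p = 0.831), and without wild type arrays 1 and 2 it was 0.34 (adjusted p = 0.18), with Cox6a1 at 2.31 (adjusted p = 0.0511 by limma). Ndufv1 did not pass without wild type array 1 or any 1 VE array, at adjusted p from 0.0695 to 0.0862. Fatty acid oxidation genes were higher at 11 of 20 and lower at 0, while 9 did not pass (14 adjusted over the list alone), with a median of 1.26 (camera adjusted p = 4.95e-08; adjusted p = 0.3 with an estimated correlation). Slc25a20 was higher by 2.33 ± 0.28 and Cpt1a by 1.77 ± 0.23, while Etfa (0.28 ± 0.28) and Ehhadh (0.32 ± 0.39) did not pass. Lep was higher by 4.16 ± 0.69, and Adipoq (0.70 ± 0.28; adjusted p = 0.111 by limma), Pparg (0.73 ± 0.47), Ucp1 (0.10 ± 0.32), Fasn (0.41 ± 0.65) and Slc2a4 (0.71 ± 0.51) did not pass. Adipoq (1.00, adjusted p = 0.0146 by limma) and Pparg (1.29, adjusted p = 0.0267) passed without wild type array 3. That fit keeps wild type arrays 1 and 2, with adipocyte identity medians of 12.54 and 12.69, against 14.38 on array 3. An increase in VE can thus not be told apart from less adipocyte signal on those arrays. The epithelium list moved with these groups, at −2.91.

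Of the epithelium list, 12 members were lower, 0 were higher and 4 did not pass (14 adjusted over the list alone; limma camera adjusted p = 2.89e-08; adjusted p = 0.286 with an estimated correlation). Against wild type array 3 alone the list's median difference was −1.4. Cdh1 was lower at −7.12 ± 0.86 (SE, n = 3) and Epcam at −6.61 ± 0.40, while Krt14 (0.09 ± 0.39) and Krt10 (−0.22 ± 0.23) did not pass. The largest increases also held Slc5a7 (9.99 ± 0.67), Tm4sf19 (8.86 ± 0.46), Atp6v0d2 (8.79 ± 0.57) and Gpr50 (7.60 ± 1.32). The largest decreases were those of Serpina1f, a serpin (−10.27 ± 2.66), Ptgs2 (−10.03 ± 2.73), Cuzd1 (−9.19 ± 1.5), Pdzk1ip1 (−8.68 ± 0.36), Cnn1 (−7.84 ± 1.70), Anxa13 (−7.82 ± 1.94), Prom1 (−7.66 ± 0.64) and Plac8 (−7.55 ± 1.73). Serpina1f and Ptgs2 rest on wild type arrays 1 and 2: without both they stood at −2.23 (adjusted p = 0.23 by limma) and −1.87 (adjusted p = 0.404). The calls of Serpina1f, Ptgs2 and Anxa13 also ended without wild type array 1, wild type array 2 or any 1 VE array, at adjusted p from 0.0518 to 0.0927 by limma. Wild type signal was uneven as well for Cuzd1 (13.67 ± 4.07, SD, n = 3), Cnn1 (12.80 ± 4.49), Plac8 (13.78 ± 4.67) and Anxa13 (11.50 ± 5.29). The sizes of these decreases thus depend on the wild type arrays used.

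In all, 3920 clusters passed by limma between VE-treated and wild type mice, 2436 higher and 1484 lower, and 2193 and 1174 of these differed more than 2-fold. At the submitters' threshold 3586 were higher and 3044 lower, and groups did not overlap at 37.2% of clusters, against 10% by chance. Camera called 13 lists, 10 higher and 3 lower, 0 with an estimated correlation, and fry called 16. Besides those above, the called lists were cell division (median 1.49, 13 of 19 higher), inflammatory cytokines (1.00, 12 of 27 higher and 1 lower), extracellular matrix (1.18, 14 of 29 higher and 1 lower), adipokines (0.87, 5 of 15 higher), adipocyte identity (0.72, 7 of 18 higher), the unfolded protein response (0.52, 4 of 17 higher), visceral depot patterning (−0.87, 3 of 11 lower) and epididymis and testis (−1.31, 4 of 19 lower). Their camera adjusted p ranged from 2.89e-08 to 0.0146, and from 0.286 to 0.506 with an estimated correlation. Without wild type arrays 1 and 2, 2774 clusters passed, 2031 of them among the 3920, and 7 lists were called. The 6 lists no longer called were adipokines (−0.043, adjusted p = 0.126), adipocyte identity (0.24, 0.407), oxidative phosphorylation (0.34, 0.18), the unfolded protein response (0.33, 0.0628), visceral depot patterning (−1.02, 0.12), and epididymis and testis (−0.38, 0.12). The unfolded protein response was not called without wild type array 1 (0.0592), nor visceral depot patterning without VE array 2 (0.0571) or wild type array 2 (0.0516). Newly called by camera were fatty acid synthesis (0.98, 0.00264), lipolysis (0.94, 0.0034) and brown and beige adipocyte genes (0.39, 0.0421) without wild type array 3, and fatty acid synthesis (0.62, 0.0347) and mesothelium (−0.97, 0.00603) without VE array 3. The count was 2314 without VE array 1 and 2342 without VE array 2, and 392 with the epithelium list mean as a covariate.

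The same ob/ob vehicle arrays enter the first and second comparison, so the share of ob/ob differences that VE moved back toward wild type was set beside simulations in which VE equals vehicle. Of 2754 clusters that differed between ob/ob vehicle and wild type, 1392 moved the opposite way in VE, a share of 50.5% (95% exact Clopper-Pearson interval 48.7 to 52.4, which takes genes as independent). The simulated share with no effect of VE was 61.1% (59.3 to 62.8 over 100 draws). These draws took the observed group means as true and a gene's spread as equal in all groups, and they gave a mean of 4747 ob/ob calls against 2754 observed, so their share is only a rough reference. The covariance of both comparisons over all genes was 0.0135, against −0.0743 in the simulation. With 1 ob/ob vehicle array held out of the calls and used for the VE difference, the share was 42.4, 54.1 and 36.7% (mean 44.4). The held-out array does not enter these calls, so the simulated 61.1% is no reference for these shares. With no effect of VE, either direction would be equally likely there, and the 3 shares lay on both sides of an even split. Clusters higher in ob/ob vehicle than in wild type had a median VE difference of −0.017, and lower ones had −0.0067. Of the 1766 clusters higher in ob/ob vehicle than in wild type, 1629 were also higher in VE than in wild type, where independent lists would share 220. Of the 988 lower ones, 842 were also lower, where independent lists would share 74.9, and 0 were called in opposite directions. Both comparisons share the wild type arrays, which adds covariance with no effect at all: it was 0.0734 in simulations with no difference between groups, against 1.18 observed, and 3 wild type arrays are too few to give each comparison its own.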

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

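Chosen only after the result was seen were the tests on the epithelial and epididymal transcripts, on the oxidative phosphorylation list and on the macrophage list, while the regroupings of arrays were planned.

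Of the 2634 transcript clusters without a gene symbol here, which the comparisons do not use, 137 were higher in ob/ob vehicle than in wild type mice by limma at an adjusted p under 0.05 over all 22206 clusters, and 133 were lower. The 270 together are 10.3% of them, against 13.9% of named clusters. Between VE and ob/ob vehicle 0 of these clusters passed, and between VE and wild type 433 did. This is a signal in data that the comparisons leave out, and no explanation was tested.

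The first pattern is the epithelial and epididymal signal of the wild type arrays. Epididymal tissue in the sample of wild type array 2 may be a source: 5 of 19 members of the epididymis and testis list lay more than 2 (log2) above the highest ob/ob array there, with Adam7 at 17.1 and Ces5a at 15.5, and 0 of these 19 and 0 of the 16 epithelium genes exceeded the array median on all 6 ob/ob arrays. Whether the sample of wild type array 1 held the same epididymal tissue stays open: of 6 members that stood so high on array 1 or 2, only 2 did on both, Odf1 (13.23 on array 1 and 11.49 on array 2) and Rnase12, while Prm2 did on array 1 alone, and the list's medians were 5.58 and 5.80. Genotype alone does not account for the spread of the epithelium list within wild type. Its medians were 8.23, 8.32 and 5.74 on the wild type arrays, which share a genotype, against 4.24 to 4.68 on the ob/ob arrays. For the part common to all wild type arrays, a difference of genotype in the adipose tissue stays open. It cannot be told apart from tissue taken along in wild type samples alone. The lowest wild type median of the epithelium list lay 1.06 above the highest ob/ob one, so the design has no wild type array free of the epithelial signal. For the epididymal transcripts array 3 speaks rather against genotype, as its list median of 4.76 lay −0.17 from the highest ob/ob one and inside their range of 4.29 to 4.93, but Adam7 stood high there too and these genes lie near the floor, so this also stays open.

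The second pattern is the higher oxidative phosphorylation list in VE than in ob/ob vehicle. A trend with genomic span that differs between arrays was argued against, since the median difference was 0.536 with each array's trend removed, against 0.547 before, and the list was still called. Genomic span is not transcript length, so this says nothing on a trend with transcript length, which was not tested. Differences between arrays of a group stay open: the lowest median with 1 array left out was 0.398, and the list's camera call held with each of the 6 arrays left out, but not with an estimated correlation (adjusted p = 0.396). The ob/ob vehicle arrays spanned 0.88 in the list's median, the VE arrays 0.33, and the lowest VE array lay 0.07 above the highest ob/ob vehicle array, so 3 arrays a group cannot tell an effect of VE, which is a hypothesis, apart from this spread. Cytosolic and mitochondrial ribosomal protein genes, families chosen after seeing the data, had medians of 0.51 and 0.40. In these 0 genes passed limma's threshold, and camera with an estimated correlation gave an unadjusted p of 0.0724 and 0.0535. By that test a shift was shown neither for them nor for the oxidative phosphorylation list. No explanation common to all 3 was tested.

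The third pattern is the higher macrophage list in ob/ob vehicle than in wild type mice. Fewer cells of the main type would raise all other cell types alike and was argued against, since the macrophage median lay 4.20 above that of the stromal progenitor list and further above that of the endothelium list, with an SD over members of 2.78, 1.15 and 0.775. These were the other cell type lists with at least 10 members over the array median on all 6 ob/ob arrays, whereas other leukocyte lists lay too low to tell. Dilution of wild type samples by epithelial tissue as the whole cause was argued against, since the macrophage median lay 4.17 above that of the adipocyte identity list (SD over members 1.48), which such tissue would dilute alike, and wild type array 3, with the least epithelial signal, had a macrophage median of 8.29 against at least 12.1 on the ob/ob arrays. More macrophages and a change within macrophages cannot be told apart in bulk tissue: the members' differences spanned 11.03, from −0.97 to 10.1, while general markers such as Adgre1, Csf1r and Cd14 were higher together with Gpnmb, Trem2 and Itgax, so a mixture of both could hold.

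For the comparisons of 3 against 3 arrays, 10 splits are too few for a share under 0.05. The count was 2754 for ob/ob vehicle against wild type, 5 for VE against ob/ob vehicle and 3920 for VE against wild type, each the highest of its 10 splits (1 of 10), and the highest of the other splits was 0 in each case. For gene lists, the real counts of 12, 4 and 13 compare with highest other counts of 17, 10 and 22, and 4, 9 and 4 of the 10 splits gave as many. The numbers of lists called thus do not set the real groups apart from other splits. The moderated F count of 3069 was the highest of 100 regroupings of the 9 arrays (1 of 100), with 2831 as the highest other. That other was the only one drawn that kept the 3 wild type arrays together, and it mixed VE with vehicle arrays. The 98 that parted the wild type arrays gave at most 2. The count thus rests on the wild type arrays standing apart, which 1 such regrouping cannot test, and it says nothing on VE.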

How the results depend on the processing

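Chosen after seeing the data were the fits without wild type arrays 1 and 2, with the epithelium list mean as a covariate and with the genomic span trend removed; all other alternatives were planned. Of the 84 gene results past the threshold, all 84 also passed under array weights, a trended prior, quantile normalization, every cluster tested, the dimmest 30% left out and the span trend removed, 83 passed under median centring, 79 under a robust prior, 78 without wild type arrays 1 and 2, 77 with only the 2 groups compared and 70 without empirical Bayes. With the covariate only 27 passed, 46 did not and 11 reversed. Of 29 list calls, 28 held under array weights and a trended prior, 22 with the dimmest 30% left out, 21 by fry, 20 after quantile normalization, 18 without wild type arrays 1 and 2, 12 with the covariate and 0 with an estimated correlation. The F count of 3069 was 164 with the covariate, 1645 without empirical Bayes, 5777 at the submitters' threshold, 2004 without wild type arrays 1 and 2, and 2105 to 3687 with 1 array left out. The ob/ob vehicle against wild type count of 2754 was 362 with the covariate, 1675 without empirical Bayes, 1814 with only the 2 groups compared, 5555 at the submitters' threshold, and 1641 (without ob/ob vehicle array 2) to 3545 (without wild type array 3). The VE against ob/ob vehicle count of 5 was 17 at an adjusted p under 0.1, 41 with array weights (39 higher, 2 lower), 8 with the covariate, 0 without empirical Bayes, 19 with only the 2 groups compared, 12 with a robust prior, 893 at the submitters' threshold (which adjusts for nothing), 19 without wild type arrays 1 and 2, and 0 (without ob/ob vehicle array 2 or any 1 VE array) to 21 (without ob/ob vehicle array 1), with 1 without ob/ob vehicle array 3 and 9 without wild type array 3. The VE against wild type count of 3920 was 392 with the covariate, 2536 without empirical Bayes, 6630 at the submitters' threshold, and 2314 (without VE array 1; 2342 without VE array 2) to 4706 (without wild type array 3). With the replicate number as a replicate block the counts were 2788 (F), 2572, 0 and 3731, 79 of the 84 gene results passed, the 5 others being the VE calls, and all 29 list calls held; deviations of same-numbered arrays correlated between −0.06 and 0.18, and 3 of 6 arrays at most matched their own number best. Lists called between ob/ob vehicle and wild type, 12, were 0 with an estimated correlation and 9 to 15 with 1 array left out. The 4 lists between VE and ob/ob vehicle were 1 with the dimmest 30% left out, 0 with an estimated correlation, 0 by fry, 1 after quantile normalization, and 2 (without VE array 3) to 11 (without VE array 1). The 13 lists between VE and wild type were 0 with an estimated correlation, 7 without wild type arrays 1 and 2, and 12 to 16 with 1 array left out. The share of 50.5% ranged from 43.9 (without VE array 3) to 62.5 (without ob/ob vehicle array 3; 59.4 without array 1) with 1 array left out. A gene's difference or a list's direction in camera turned, in results past the threshold before or after, only with the epithelium list mean as a covariate, which nearly coincides with genotype, so its slope rests on the 3 wild type arrays. Camera's direction need not be that of the median, which is what is given for lists (ob/ob vehicle, then VE, against wild type): Anxa13 6.84 and 6.35, Cnn1 4.18 and 4.15, Lep −0.60 and −0.75, adipocyte identity −0.778 and −0.335, adipokines −0.599 and −0.727, endothelium −1.42 and −1.32, epididymis 0.509 and 0.271, epithelium 0.0459 and −0.244, fatty acid synthesis −1.34 and −1.20, insulin signalling −0.854 and −0.924, lipolysis −1.45 and −1.16; against wild type in ob/ob vehicle alone Kif5c 7.01, fatty acid oxidation 0.0472 and visceral depot patterning −0.291; in VE alone Gpx3 0.574, Plac8 4.51, Ptgs2 8.95 and Serpina1f 8.31. Of these, the medians of fatty acid oxidation, of visceral depot patterning and of epithelium in VE kept their sign. Medians of called lists also changed sign, with the call lost, with the covariate (extracellular matrix −0.143 and −0.0105, oxidative phosphorylation in VE −0.153), without wild type arrays 1 and 2 (adipokines −0.363 and −0.0433, epididymis 0.0467 in ob/ob vehicle), without ob/ob vehicle array 1 (adipokines −0.0433 in ob/ob vehicle) and, for NRF2 between VE and ob/ob vehicle, without ob/ob vehicle array 3 (−0.107). Fits with an array left out have fewer samples, yet counts against wild type rose without wild type array 3; for these and the other changes the cause was not tested. Median centring moved the median of all VE against wild type differences from −0.067 to 0.04, a shift of over 0.1 that applies to small differences there. Robust and ordinary fits were not run for camera, nor the 2-group fit for the F test. Signal over background, which limits dim clusters, is unknown here.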

Other observations

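Chosen after seeing the data were the genes and gene families named here, and none of the values was tested as an explanation.

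Of 63 genes of cytosolic ribosomal proteins, 54 were higher in VE than in ob/ob vehicle, with a median log2 difference of 0.51 and 0 past limma's adjusted threshold (893 of all clusters had an unadjusted p under 0.05). Limma's camera gave an unadjusted p of 4.13e-22 at its preset correlation and of 0.0724 with an estimated correlation. By the latter a shift of the group was not shown. Nor was one shown by it for the oxidative phosphorylation list, with a median of 0.55 (camera adjusted p = 0.396 with an estimated correlation). Of 76 mitochondrial ribosomal protein genes, 65 were higher, with a median of 0.40 and 0 past the threshold, and camera gave an unadjusted p of 4.64e-17 at its preset correlation and of 0.0535 with an estimated one.

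4 genes of plasma proteins read lowest on wild type array 2. Albumin Alb read 12.5 on wild type array 2 and between 17.8 and 19.7 on the other 8 arrays, and transthyretin Ttr read 6.69 there and 12.7 to 16.0 elsewhere. Apoa1 read 5.28 and Ahsg 7.60 on that array, with up to 14.1 and 15.1 on wild type array 3. The lymphatic chemokine Ccl21a read 11.46, 12.05 and 13.04 on the wild type arrays, 10.4 on ob/ob vehicle array 3 and 9.67 on VE array 1, and 5.55 to 7.22 on the other 4 ob/ob arrays. It was lower in ob/ob vehicle than in wild type mice by limma (−4.06 ± 1.16, SE, n = 3; adjusted p = 0.0426). Of the sperm transcripts on the epididymis and testis list, Odf1 read 13.2 and 11.5 on wild type arrays 1 and 2 and 5.55 on array 3, and Prm2 read 11.6, 7.91 and 6.04.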
